A study of Homo sapiens with 9 samples.

How the data were processed

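The samples were total RNA from LNCaP cells at 0 h, 4 h and 16 h of DHT, labelled with biotin and hybridised to oligonucleotide arrays, 3 arrays per time. The labels call the samples biological replicates. The values analysed were the deposited signal intensities on a linear scale, 1 per probe set and array. The authors' software was GCOS per the submitters' processing notes, whose version is not given there; the summary method, the scaling target and any detection calls are not given in the sources used here. The deposited intensities had a trimmed mean, leaving out 2% at each end, of 500.05 to 500.06 on every array. The arrays had therefore already been scaled alike and were used without further normalization.

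Intensities were taken to log2. The annotation table covered 54675 probe sets, of which 62 were controls. Of the 54613 others, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Symbols were updated through the Entrez gene identifier for 41043 probe sets. Probe sets whose mean log2 intensity over the 9 arrays lay above the median of 7.03 (a signal of 130.7) were kept, 27306 in all. Of these, 22693 had a single usable symbol, and each gene was represented by its probe set with the highest mean, which gave 12461 genes. For 5844 of them over 1 probe set passed the filter. Of 9 genes that were to be named whatever their result, 7 had a named probe set; the others are not reported here.

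The test was limma's linear model with 1 mean per time over all 9 arrays, so that the comparisons shared 6 residual degrees of freedom, followed by empirical Bayes moderation with a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over all genes in a comparison, with a threshold of 0.05. An F test asked which genes differed over the 3 times. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data; each adjusted list p was corrected over 26 lists. Before the data were examined, 27 lists were fixed, of which 26 had at least 5 measured genes. The comparisons, the tests, the lists and the rule for named genes were also fixed then. That rule took, per comparison, the 8 largest rises and 8 largest falls among called genes whose 3 arrays in each group did not overlap, up to 4 members of each list with the smallest adjusted p, a short set of reference genes, and the 6 genes with the largest return between 4 h and 16 h. With 3 arrays against 3, chance separates the groups of 10% of genes.

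A lower bound was used for dim genes, a choice made after seeing the data. A gene was taken to lie at background in a group when all 3 arrays were at or below the 95th percentile of 27 bacterial control probe sets that were not added to the samples. The fold against such a group was computed against that percentile and is written as at least that fold. The percentile was a signal of 52.1 to 112.1 on the 9 arrays.

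Pairs of arrays correlated closely: the mean r of an array with the others in its group ran from 0.973 to 0.976, and no arrays held identical values. The ratio of 3' to 5' signal ran from 0.850 to 0.938 for GAPDH and from 1.30 to 1.43 for ACTB. The 28S ribosomal control signal was 694.8 ± 311 at 0 h, 935.0 ± 460 at 4 h and 454.4 ± 84.2 at 16 h (SD, n = 3).

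The fit was tested on simulated data with the real means and spreads of the 12461 genes, in which 200 genes changed by known amounts, 5 simulations per comparison. At a log2 change of 0.5 the test recovered 40.4% of changed genes for 4 h against 0 h, 41.2% for 16 h against 0 h and 46.0% for 16 h against 4 h. At a log2 change of 1 it recovered 76.8%, 84.0% and 74.8%. False calls made up 5.60%, 4.73% and 5.48% of calls. The list test called each of 5 lists of 40 genes shifted by 0.3 and 0 of 250 unshifted lists in every comparison; genes were simulated as independent, which favours the preset correlation.

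The alternatives fixed at the same time as the tests were quantile normalization, median scaling, no filter, an upper-third filter, a pseudocount of 32, the replicate number as a block, no mean-variance trend, the mean of a gene's probe sets, array weights, only the groups compared, each array left out in turn, an adjusted p under 0.01, a fold of at least 1.5 and an estimated correlation. Families of metallothioneins, zinc transporters and glycosylation genes were added after seeing the data. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. Sex-linked marker genes and probe sets with several or no symbols were left out of the gene tables.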

Results

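Messenger RNA was measured in LNCaP, an established cell line from a human prostate cancer that responds to androgen, before and after treatment with the androgenic steroid hormone DHT (dihydrotestosterone). Cells were sampled at 0 h, 4 h and 16 h, with 3 biological replicates and so 3 arrays at each time. Each of the 9 arrays carried 54675 probe sets, and 12461 genes with a named probe set above the signal filter were tested. Array precision was limited by the number of arrays. Gene signals are given as mean ± SD over 3 arrays, and log2 fold changes are given ± SE from limma. The dose is not given in the sources used here, and the design has no untreated cells at 4 h or 16 h, so time in culture and DHT exposure cannot be told apart.

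The first comparison asked which transcripts responded within 4 h of DHT. TMPRSS2, a transmembrane serine protease, rose 10.1-fold from a signal of 1272 ± 209 to 12740 ± 1058 (log2 change 3.34 ± 0.13, adjusted p = 7.78e-09). KLK2, a secreted kallikrein protease, rose 8.90-fold from 543.5 ± 49.8 to 4841 ± 509 (log2 change 3.15 ± 0.12, adjusted p = 7.78e-09). KLK3, which encodes prostate-specific antigen, rose 2.09-fold from an already high 10930 ± 1306 to 22710 ± 622 (adjusted p = 2.44e-05). FKBP5, a co-chaperone of steroid receptors, rose 3.85-fold (log2 change 1.94 ± 0.23, adjusted p = 0.000497).

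In all, 146 genes were higher and 44 were lower at 4 h than at 0 h by limma with Benjamini-Hochberg adjustment, and 44 of the higher and 2 of the lower changed at least 2-fold. Other large rises at 4 h were those of SGK1, a serum- and glucocorticoid-regulated kinase (10.8-fold, log2 change 3.44 ± 0.45), and SNAI2, a transcriptional repressor (9.56-fold, 3.26 ± 0.33). PMEPA1, an inhibitor of TGF-beta signalling, rose 5.51-fold (2.46 ± 0.11), and F5, coagulation factor V, rose 6.06-fold (2.60 ± 0.43). The F5 rise was 9.51-fold without 0 h replicate 2, and its call ended without a mean-variance trend (adjusted p = 0.0577). With a pseudocount of 32 the rises of SGK1 and SNAI2 were 7.09-fold and 6.31-fold. CTBP1-AS did not exceed background on any 0 h array and rose at least 4.31-fold (adjusted p = 9.22e-05). IGKC also lay at background at 0 h and was at least 3.67-fold higher (adjusted p = 0.0448). Its call ended without 0 h replicates 1, 2 or 3 (adjusted p = 0.081, 0.0963 and 0.15), 4 h replicates 1 or 3 (0.22 and 0.152) or 16 h replicate 3 (0.0598). Other settings that ended it included quantile normalization (0.0603), no filter (0.0876), no mean-variance trend (0.138), the mean of probe sets (0.059) and array weights (0.0577).

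Falls at 4 h were smaller. OPRK1, the kappa opioid receptor, fell 2.13-fold from 4039 ± 260 to 1895 ± 69.2 (log2 change -1.09 ± 0.16, adjusted p = 0.00224). BAMBI, a TGF-beta pseudoreceptor, fell 1.96-fold (-0.97 ± 0.09, adjusted p = 6.88e-05). ZNF703 fell 1.93-fold, OSR2 1.87-fold, ZBTB43 1.65-fold and PITX1 1.62-fold, all transcriptional regulators. AMIGO2 was 2.28-fold lower (adjusted p = 0.0212) and LRIG3 1.71-fold lower (adjusted p = 0.0451). The AMIGO2 call ended without 0 h replicates 1, 2 or 3 (adjusted p = 0.0717, 0.0723 and 0.0922) or 4 h replicates 1 or 2 (0.0926 and 0.0799). The LRIG3 call ended when any of the 9 arrays was left out, with an adjusted p between 0.0531 (4 h replicate 3) and 0.176 (4 h replicate 2). The count of 44 lower genes was 21, 24, 27, 23 and 26 without 0 h replicate 1, 4 h replicate 1, 0 h replicate 2, 4 h replicate 2 and 0 h replicate 3. Other settings that ended the LRIG3 call included no filter (0.0861) and only the groups compared (0.0646). Without a mean-variance trend in limma, 92 genes were higher and 18 lower, and AMIGO2 and ZBTB43 were not called (adjusted p = 0.0633 and 0.078).

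Gene lists fixed before the data were examined described the same comparison by function. Of 41 measured androgen-induced genes, 23 rose at 4 h, none fell and 18 did not pass the test (31 rose and 1 fell when adjusted over the list alone). The median log2 change of this list was 0.98 (camera adjusted p = 3.59e-57, and adjusted p = 0.0266 with an estimated correlation). C1orf116 rose 3.07-fold (log2 change 1.62 ± 0.06) and SLC45A3, the prostate membrane protein prostein, rose 3.14-fold (1.65 ± 0.11). The list came from general knowledge of androgen-treated prostate cells, which can include experiments such as this one, and is not independent evidence of its direction. Of 20 measured androgen-repressed genes, 2 fell, OPRK1 and PIK3R3 (1.31-fold, -0.39 ± 0.07), and 18 did not pass the test (3 fell when adjusted over the list alone). The PIK3R3 call ended without a mean-variance trend (adjusted p = 0.0723). That list had a median of -0.17 (camera adjusted p = 0.00278, and adjusted p = 0.868 with an estimated correlation).

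Genes for building ribosomes shifted slightly downward together at 4 h, with no single member past the test over all genes or adjusted over the list alone. Of 45 measured members, 38 had negative changes and the median was -0.10 (camera adjusted p = 0.00266, and adjusted p = 0.858 with an estimated correlation). The member with the smallest adjusted p, NOLC1, a nucleolar phosphoprotein, changed by -0.24 ± 0.07 (adjusted p = 0.118). The other 23 lists tested were not called at 4 h, but single members of several passed the test. Of 33 measured Wnt and growth factor receptor genes, 5 rose and none fell (6 and 2 when adjusted over the list alone; list adjusted p = 0.35). Among them, the Wnt receptor FZD5 rose 2.55-fold (1.35 ± 0.12), the insulin receptor substrate IRS2 rose 3.12-fold (1.64 ± 0.18) and IGF1R rose 2.59-fold (1.38 ± 0.20). The fatty acid elongase ELOVL7 rose 2.49-fold (1.32 ± 0.13), the glucose transporter SLC2A12 rose 2.39-fold (1.26 ± 0.11) and ERN1, the endoplasmic reticulum stress sensor IRE1, rose 2.22-fold (1.15 ± 0.14). Among 33 transcription factors and coregulators linked to androgen action, GRHL2 rose 2.21-fold (1.14 ± 0.12) while GATA2 fell 1.50-fold (-0.59 ± 0.09). Of the probe sets for ERN1 and for GATA2, 1 of 3 was called, as were 2 of 3 for KLK3 and 3 of 5 for ZBTB43; the others had the same sign. FOXA1, of the transcription factor group, had a log2 change of 0.00 ± 0.06 (adjusted p = 0.99).

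**Figure D1:**
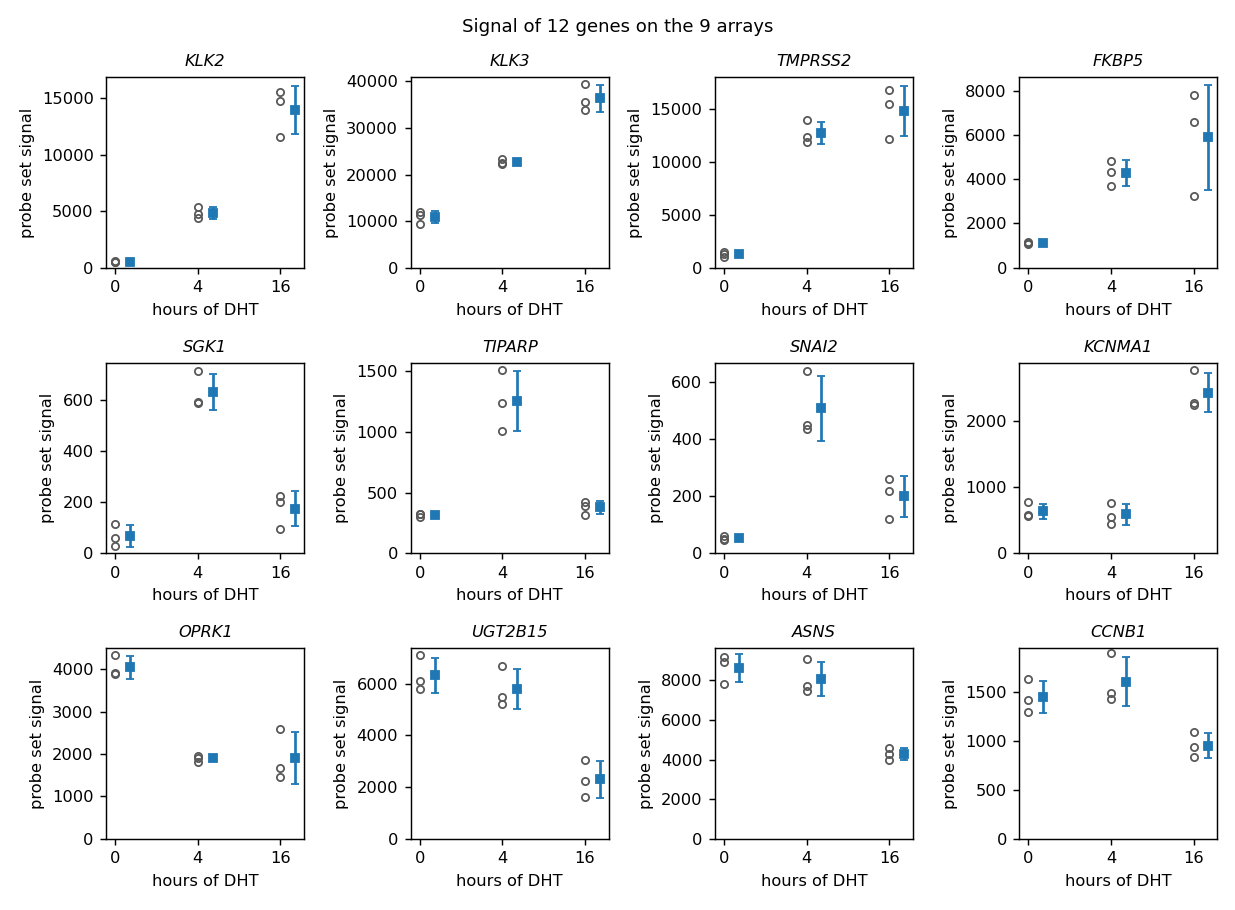
Probe set signal (vertical axes, linear, starting at 0) of 12 genes against hours of DHT, with the 3 times drawn at equal distances; open circles are the 3 arrays of a time and squares with bars are their mean and SD. KLK2 and KLK3 were highest at 16 h, SGK1, TIPARP and SNAI2 were highest at 4 h, and ASNS, CCNB1 and UGT2B15 were lowest at 16 h.

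The second comparison asked which transcripts differed after 16 h. KLK2 rose 25.6-fold over 0 h, to a signal of 13960 ± 2119 (log2 change 4.68 ± 0.12, adjusted p = 6.59e-11). TMPRSS2 rose 11.7-fold (3.55 ± 0.13), PMEPA1 8.05-fold (3.01 ± 0.11), FKBP5 4.99-fold (2.32 ± 0.23) and KLK3 3.34-fold (1.74 ± 0.09). TRPM8, a cold-sensing cation channel, lay at background at 0 h and rose at least 7.70-fold (adjusted p = 5.24e-05). ST6GALNAC1, a sialyltransferase, rose 8.91-fold (3.16 ± 0.52, adjusted p = 0.00208; 5.29-fold without 0 h replicate 2 and 5.33-fold with a pseudocount of 32), and HPGD, which inactivates prostaglandins, rose 6.13-fold (2.62 ± 0.48, adjusted p = 0.00432). CTBP1-AS was at least 4.28-fold higher and F5 was 6.95-fold higher (2.80 ± 0.43), or 10.9-fold without 0 h replicate 2.

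Over all genes, 444 were higher and 543 lower at 16 h than at 0 h (limma, Benjamini-Hochberg), of which 78 and 43 changed at least 2-fold. MT1H, a metal-binding metallothionein, fell 6.14-fold (-2.62 ± 0.51, adjusted p = 0.00633, but 0.0504 without a mean-variance trend). FHOD3, an actin regulator, fell 4.01-fold (-2.00 ± 0.42), and MAN1A1, a mannosidase of the Golgi, fell 3.14-fold (-1.65 ± 0.21). Further large falls were less secure. They were those of ADCY6-DT (4.45-fold), CKAP2L (3.89-fold), LRRC31 (3.72-fold), DUS2 (3.63-fold) and CDH26 (3.20-fold). The ADCY6-DT call ended without any array but 16 h replicate 3, with an adjusted p from 0.0533 (4 h replicate 3) to 0.147 (16 h replicate 2). The CKAP2L call ended without 0 h replicates 1, 2 or 3 (0.095, 0.0632 and 0.0797) or 16 h replicates 2 or 3 (0.115 and 0.0966), and the LRRC31 call without 0 h replicates 1 or 3 (0.059 and 0.0551). The DUS2 call ended without 0 h replicates 1 or 3 (0.064 and 0.0528) or 16 h replicates 1 or 2 (0.0678 and 0.0663), and 1 of its 2 probe sets was called. The CDH26 call ended without 0 h replicates 1, 2 or 3 (0.0697, 0.095 and 0.0688), and 2 of its 3 probe sets had its sign.

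Without 16 h replicate 3 the fall was 8.57-fold for ADCY6-DT and 5.69-fold for DUS2, and the log2 change of CDH26 was -1.003; without 16 h replicate 1 it was 6.47-fold for CKAP2L. With the mean of probe sets it was 1.93-fold for DUS2 and for CDH26, and the ADCY6-DT call ended (adjusted p = 0.0558). The calls of ADCY6-DT, CKAP2L, DUS2 and CDH26 ended without a mean-variance trend (0.121, 0.0919, 0.0841 and 0.105). Those of ADCY6-DT, CKAP2L and CDH26 also ended with no filter (0.0745, 0.0589 and 0.0579) and with only the groups compared (0.0771, 0.059 and 0.0514). The count of lower genes was 317 without 0 h replicate 1, 329 without 16 h replicate 2 and 353 without 0 h replicate 3, and 294 genes were higher without 16 h replicate 2. Without a mean-variance trend 303 genes were higher and 289 lower. Without 0 h replicate 1, 368 genes were higher, so in both of these settings rises outnumbered falls.

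Both androgen lists were also called at 16 h. Of 41 androgen-induced genes 30 rose and none fell (34 when adjusted over the list alone; median log2 change 1.27, camera adjusted p = 2.54e-48, and adjusted p = 0.0415 with an estimated correlation). Of 20 androgen-repressed genes 11 fell and none rose (14 when adjusted over the list alone; median -0.59, camera adjusted p = 4.1e-12, and adjusted p = 0.133 with an estimated correlation). UGT2B15, which conjugates androgens for removal, fell 2.83-fold from 6339 ± 676 to 2304 ± 722 (-1.50 ± 0.18, adjusted p = 0.000151). Its relative UGT2B17 fell 2.18-fold (-1.12 ± 0.16, adjusted p = 0.000875), and the chemokine receptor ACKR3 fell 1.68-fold (-0.75 ± 0.08). Of 17 luminal prostate epithelium markers 5 rose and none fell (6 when adjusted over the list alone; median 0.14, camera adjusted p = 0.00034, and adjusted p = 0.133 with an estimated correlation), among them SLC45A3 (4.03-fold) and the keratin KRT8 (1.43-fold, 0.51 ± 0.08). Of these markers 10 had positive and 7 had negative changes, with a mean of 0.46. KLK3 and SLC45A3 are also on the androgen-induced list, so the luminal list call in part restates the call of that list.

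Genes of cell division were lower at 16 h. Of 59 measured G2/M and mitosis genes, 16 fell and none rose (37 fell when adjusted over the list alone), and 58 had negative changes. Their median log2 change was -0.55 (camera adjusted p = 4.48e-15, and adjusted p = 0.334 with an estimated correlation). TPX2, a spindle assembly factor, fell 1.66-fold (-0.73 ± 0.14, adjusted p = 0.007). CDC20, an activator of the anaphase-promoting complex, fell 1.83-fold (-0.87 ± 0.19), the spindle protein DLGAP5 fell 1.78-fold (-0.83 ± 0.18) and cyclin B1 (CCNB1) fell 1.52-fold (-0.61 ± 0.13). The adjusted p of CDC20 and CCNB1 was 0.0502 and 0.0536 without 0 h replicate 1, and that of DLGAP5 was 0.0507 without 16 h replicate 2. For CCNB1 1 of 2 probe sets was called, and the call was lost with the mean of both (0.0607) and without a mean-variance trend (0.0569). Of 45 DNA replication and G1/S genes 5 fell and none rose (6 when adjusted over the list alone; median -0.13, camera adjusted p = 0.0143, and adjusted p = 0.647 with an estimated correlation). This list was not called without 0 h replicate 1 or 16 h replicate 3 (adjusted p = 0.104 and 0.14). The nucleotide synthesis enzymes TK1 and TYMS fell 2.04-fold and 1.99-fold (adjusted p = 0.00331 and 0.00409). UBE2C, a ubiquitin-conjugating enzyme of mitosis, was 1.48-fold lower and did not pass the test (-0.57 ± 0.22, adjusted p = 0.14).

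Genes of the secretory pathway were higher at 16 h. Of 38 measured genes of the unfolded protein response and endoplasmic reticulum folding, 13 rose and none fell (18 when adjusted over the list alone; median 0.27, camera adjusted p = 1.06e-13, and adjusted p = 0.133 with an estimated correlation). EDEM3, which acts in the disposal of misfolded glycoproteins, rose 1.88-fold (0.91 ± 0.09), CREB3L4, a membrane-bound transcription factor, rose 1.81-fold (0.86 ± 0.08) and the chaperone partner DNAJB9 rose 1.80-fold (0.85 ± 0.09). Of 52 genes of transport from the endoplasmic reticulum to the Golgi and protein export, 14 rose and none fell (18 rose and 1 fell when adjusted over the list alone; median 0.14, camera adjusted p = 1.16e-07, and adjusted p = 0.2 with an estimated correlation). The signal peptidase subunits SEC11C and SPCS3 rose 1.50-fold (0.59 ± 0.07) and 1.63-fold (0.71 ± 0.11).

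ATF4 targets and tRNA synthetases went the other way. Of 38 measured members 16 fell and none rose (24 when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 9.16e-14, and adjusted p = 0.133 with an estimated correlation). Asparagine synthetase (ASNS) fell 2.02-fold from 8641 ± 714 to 4283 ± 314 (-1.01 ± 0.09, adjusted p = 1.66e-05). The serine synthesis enzymes PHGDH and PSAT1 fell 1.53-fold (-0.61 ± 0.07) and 1.47-fold (-0.56 ± 0.07).

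Among metabolic lists at 16 h, 5 of 17 polyamine genes rose and 2 fell (6 and 2 when adjusted over the list alone; median 0.07, camera adjusted p = 0.00376, and adjusted p = 0.334 with an estimated correlation). Arginase 2 (ARG2) rose 2.23-fold (1.16 ± 0.07), spermine synthase (SMS) rose 1.74-fold (0.80 ± 0.11) and SAT1, which acetylates polyamines for breakdown, rose 1.66-fold (0.73 ± 0.07). GNMT, a glycine methyltransferase that is also on the androgen-induced list, rose 2.84-fold (1.51 ± 0.28). Of 51 oxidative phosphorylation genes 3 fell and none rose, also when adjusted over the list alone (median -0.15, camera adjusted p = 2.46e-06, and adjusted p = 0.528 with an estimated correlation). No cytosolic ribosomal protein gene of 38 passed the test, over all genes or adjusted over the list alone, and the median was -0.10. Their list call (camera adjusted p = 0.00968, and adjusted p = 0.67 with an estimated correlation) was lost with quantile normalization, with the mean of probe sets, and without 0 h replicate 2 (adjusted p = 0.872) or 16 h replicate 3 (0.157). Of 19 fatty acid synthesis genes 6 rose and 3 fell (6 and 5 when adjusted over the list alone). Their median was -0.12 while their mean was 0.09 and the list test pointed up, with an adjusted p of 0.378. ELOVL7 rose 4.86-fold (2.28 ± 0.13), ELOVL5 rose 1.76-fold (0.81 ± 0.06) and SCAP, a sterol-sensing escort protein, rose 1.54-fold (0.62 ± 0.07). ACACA, a carboxylase of fatty acid synthesis, rose 1.68-fold (0.75 ± 0.07), but only 1 of its 2 probe sets had that sign and the mean of both was not called (adjusted p = 0.53).

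The remaining lists were not called at 16 h. Cholesterol synthesis had 1 of 18 genes higher and none lower (list adjusted p = 0.0502), ribosome biogenesis 1 of 45 higher (0.0602) and p53 targets 4 of 25 lower (0.0543). Hypoxia targets had 2 of 23 higher and 4 lower (0.552), with NDRG1, which is also on the androgen-induced list, up 2.46-fold (1.30 ± 0.14). Immediate early genes had 3 of 28 higher and 2 lower (0.92), with MYC up 1.40-fold (0.49 ± 0.08). Glycolysis had 2 of 24 higher and 1 lower (0.802), interferon response 1 of 31 each way (0.896), steroid metabolism 2 of 14 higher and 3 lower (0.552), and transcription factors and coregulators linked to androgen action 2 of 33 higher and 4 lower (0.577). Of the lower steroid metabolism genes, UGT2B15 and UGT2B17 are also on the androgen-repressed list. Wnt and growth factor receptors had 5 of 33 higher and 1 lower (0.518), and neuronal markers 1 of 10 lower (0.552). The lists of fibroblast and smooth muscle markers and of leukocyte markers were not called. Fibroblast and smooth muscle markers had 1 of 12 lower (0.922) and leukocyte markers 1 of 8 higher (0.139), the actin-bundling gene LCP1 at 1.70-fold. None of 4 measured basal epithelium markers passed the test, and that list was too short for a list test. Housekeeping genes had 1 of 26 higher and 3 lower (0.143). ETV1 had a log2 change of 0.22 ± 0.07 and FOXA1 of -0.10 ± 0.06, neither past the test (adjusted p = 0.0595 and 0.396).

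**Figure D2:**
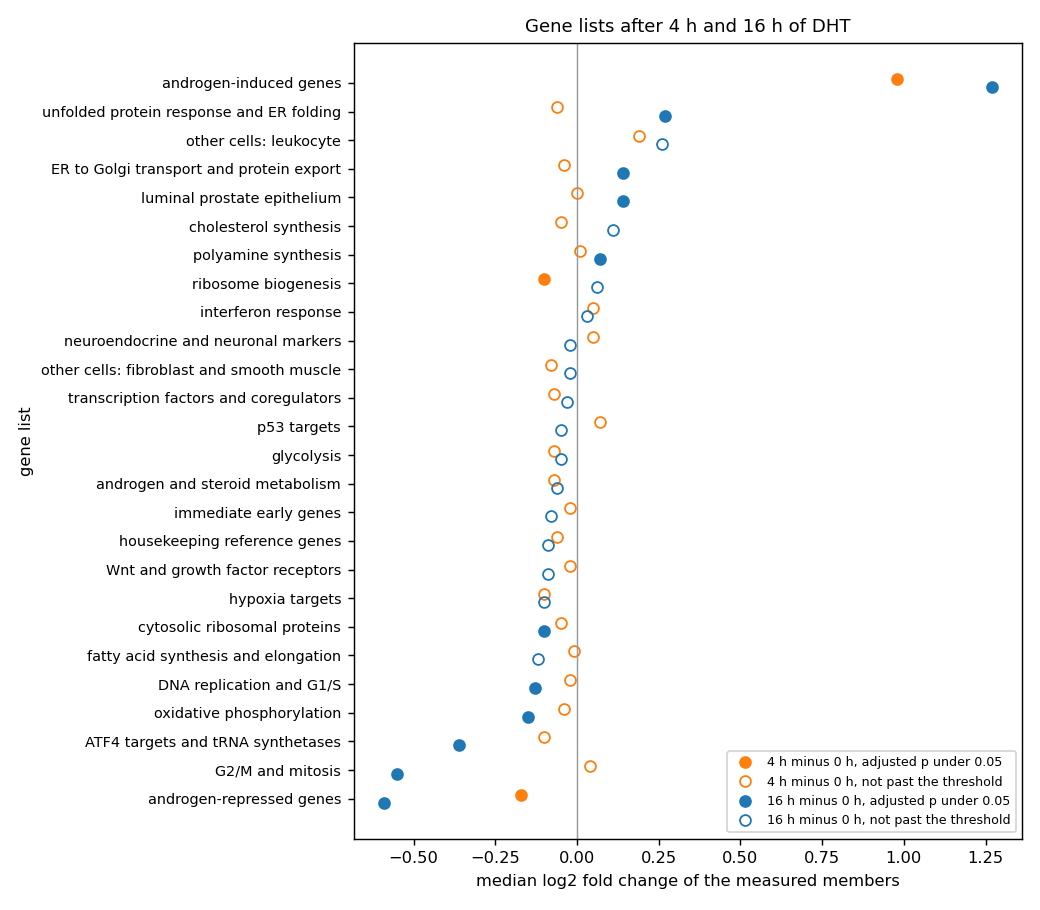
Median log2 fold change of the measured members (horizontal axis) of each of the 26 gene lists tested (vertical axis) at 4 h and at 16 h against 0 h; filled points passed the camera test at an adjusted p under 0.05 with its preset correlation and open points did not. Androgen-induced genes had the highest medians, 0.98 and 1.27, and G2/M and mitosis genes had a median of -0.55 at 16 h.

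The third comparison set 16 h against 4 h, to see which early changes grew, held or returned. KLK2 rose a further 2.87-fold between 4 h and 16 h (1.52 ± 0.12, adjusted p = 2.14e-05), KLK3 a further 1.60-fold (0.68 ± 0.09, adjusted p = 0.00128; 2 of its 3 probe sets had this sign) and TRPM8 3.80-fold (1.93 ± 0.35, adjusted p = 0.00755). The potassium channel gene KCNMA1 rose 4.22-fold, from 587.2 ± 158 to 2431 ± 296 (2.08 ± 0.18, adjusted p = 8.44e-05). TIPARP, a mono-ADP-ribosyltransferase, rose by 4 h to 1253 ± 250 and fell back 3.31-fold to 377.0 ± 57.2 by 16 h (-1.72 ± 0.17, adjusted p = 0.000182). The cell death gene PMAIP1 fell back 2.54-fold (-1.34 ± 0.21, adjusted p = 0.00393), and CDC42EP3, an effector of CDC42, fell back 1.81-fold (-0.86 ± 0.15, adjusted p = 0.0072).

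In this comparison 282 genes were higher and 268 lower at 16 h than at 4 h (limma, Benjamini-Hochberg), 16 and 33 of them at least 2-fold. Of the 146 genes higher at 4 h, 25 rose further, 22 fell back and 99 had no call between 4 h and 16 h. Of the 44 lower at 4 h, 3 fell further, 4 came back and 37 had no call. The same 4 h arrays were used to pick these genes and to compare them with 16 h. Random deviations at 4 h therefore favour a call of return over one of further change, and how much they add was not measured. SGK1, SNAI2 and IRS2 also fell back, by 3.87-fold, 2.64-fold and 1.73-fold, but less securely. Their calls ended without 4 h replicate 1 (adjusted p = 0.0808, 0.074 and 0.1), 4 h replicate 2 (0.109, 0.152 and 0.111), 16 h replicate 2 (0.0591, 0.0702 and 0.0997) and 16 h replicate 3 (0.0839, 0.0861 and 0.0741), and for SGK1 and SNAI2 also without 4 h replicate 3 (0.0687 and 0.0704). All 3 calls ended without a mean-variance trend (0.0947, 0.0549 and 0.096), as did those of SGK1 and SNAI2 with no filter (0.0536 and 0.0586). Other falls were those of MT1H (5.33-fold), ACTC1 (4.61-fold), CKAP2L (4.33-fold), CCDC60 (3.11-fold), UBXN10 (2.69-fold) and MAN1A1 (2.66-fold). Other rises were those of LOC153910 (3.36-fold), STEAP4 (2.97-fold), CSGALNACT1 (2.96-fold), IL15RA (2.95-fold) and KCTD21 (2.74-fold). Of these 11 genes, only CCDC60 and MAN1A1 kept their calls in each of the 9 single-array omissions.

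Among the falls, the call ended for MT1H without 4 h replicates 1 or 2 or 16 h replicates 2 or 3 (highest adjusted p = 0.0792), and for ACTC1 without any 4 h array or 16 h replicates 1 or 2 (0.119). It ended for CKAP2L without any 4 h array or 16 h replicates 2 or 3 (0.132), and for UBXN10 without any 4 h array or 16 h replicate 1 (0.0893). Among the rises, it ended for LOC153910 without 4 h replicates 2 or 3 or 16 h replicates 1 or 3 (0.129), and for STEAP4 without 4 h replicate 1 or 16 h replicates 1 or 2 (0.0702). It ended for CSGALNACT1 without 4 h replicates 1 or 3 or 16 h replicates 1 or 2 (0.0997). For IL15RA it ended without 0 h replicates 1 or 2, 4 h replicates 2 or 3 or any 16 h array (0.164), and for KCTD21 without 0 h replicate 3, 4 h replicates 1 or 3 or any 16 h array (0.116). Without 16 h replicate 3 ACTC1 fell 7.60-fold, and without 16 h replicate 1 CKAP2L fell 7.21-fold.

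Without a mean-variance trend the calls of MT1H, ACTC1, CKAP2L, LOC153910, STEAP4, CSGALNACT1, IL15RA and KCTD21 ended (adjusted p = 0.101, 0.104, 0.109, 0.0601, 0.0534, 0.0573, 0.0977 and 0.0954). With no filter those of ACTC1, CKAP2L, LOC153910, IL15RA and KCTD21 ended (0.0585, 0.0635, 0.0571, 0.0914 and 0.0759). With only the groups compared those of CKAP2L, LOC153910, IL15RA and KCTD21 ended (0.0666, 0.0529, 0.0715 and 0.0626), and settings that ended that of IL15RA included the mean of probe sets (0.0631). Higher genes numbered 177, 148, 166 and 123 without 4 h replicate 1, 16 h replicate 1, 4 h replicate 2 and 16 h replicate 2, and lower genes 145, 131, 120 and 166 without 4 h replicate 1, 4 h replicate 2, 16 h replicate 2 and 4 h replicate 3. Without a mean-variance trend 86 genes were higher and 93 lower.

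Of the gene lists, 14 of 26 were called between 4 h and 16 h with the preset correlation, and 0 were called with an estimated one. G2/M and mitosis genes fell, with 16 of 59 lower and none higher (43 lower and 1 higher when adjusted over the list alone; median -0.64, camera adjusted p = 4.38e-20, and adjusted p = 0.221 with an estimated correlation). The mitotic transcription factor FOXM1 fell 1.94-fold (-0.95 ± 0.17, adjusted p = 0.00755). Endoplasmic reticulum folding genes rose, with 17 of 38 higher and 1 lower (22 and 1 when adjusted over the list alone; median 0.29, camera adjusted p = 6.08e-17, and adjusted p = 0.119 with an estimated correlation). ATF4 targets fell, with 9 of 38 lower and none higher (18 when adjusted over the list alone; median -0.25, camera adjusted p = 1.77e-12, and adjusted p = 0.119 with an estimated correlation). The amino acid transporter SLC7A5 fell 2.60-fold (-1.38 ± 0.23, adjusted p = 0.00523). Ribosome biogenesis genes went up from 4 h to 16 h, with 4 of 45 higher and none lower (10 when adjusted over the list alone). Their median was 0.17 (camera adjusted p = 4.08e-07, and adjusted p = 0.119 with an estimated correlation). This rise used the same 4 h arrays as the fall at 4 h, so fall and rise are not independent. At 16 h against 0 h this list was not called (median 0.06, camera adjusted p = 0.0602).

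**Figure D3:**
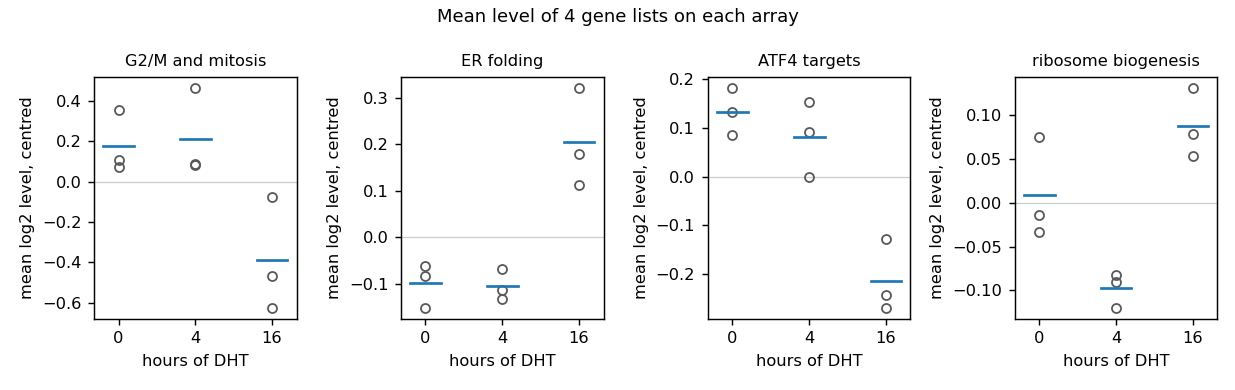
Mean log2 level of 4 gene lists on each array (vertical axes, centred on the mean of the 9 arrays) against hours of DHT; circles are single arrays and lines are the means of 3 arrays. Each of the 3 arrays at 16 h lay below every 0 h and 4 h array for G2/M and mitosis genes and for ATF4 targets, and above them for endoplasmic reticulum folding genes.

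The calls at 4 h and 16 h overlapped. Of the 146 genes higher at 4 h, 118 (80.8%) were also higher at 16 h, where independent lists would share 5.2. Of the 44 lower at 4 h, 35 (79.5%) were also lower at 16 h, where independent lists would share 1.92, and 1 gene was called in opposite directions. Both comparisons used the same 0 h arrays. The fold changes correlated across genes with r = 0.559 (0.502 on average in 100 simulations of unchanged groups with shared controls; genes are not independent replicates), and their covariance was 0.0517 against a simulated 0.0212, a difference of 0.0305. Simulated unchanged groups that shared the controls overlapped by at most 0 higher and 1 lower genes in 100 simulations; groups without change leave few called genes to overlap, so this does not measure what the shared arrays add. With 3 control arrays the controls could not be split, so part of the overlap may come from the shared arrays. Over all 3 times together, 957 genes differed by limma's F test (Benjamini-Hochberg), or 590 and 530 without 16 h replicates 1 and 2 and 493 without a mean-variance trend.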

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

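The test of whether mitosis genes merely followed differences between cultures was chosen after its list p with an estimated correlation had been seen; the other tests were chosen before their own results were seen, for patterns picked after the list results had been seen, but the use of an upper limit for shares of random lists was added after those shares had been seen.

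Results are collected here where the 16 h and 4 h effects differed by a direct test (limma or camera, Benjamini-Hochberg) and where probe sets outside the gene tables changed. Lists that camera called upward at 16 h against 4 h were androgen-induced genes (median 0.28), cholesterol synthesis (0.14) and fatty acid synthesis (0.03). Also called upward were endoplasmic reticulum folding (0.29), transport to the Golgi (0.21), polyamine synthesis (0.02), ribosome biogenesis (0.17) and luminal epithelium (0.18). Lists called downward were androgen-repressed genes (-0.43), DNA replication (-0.15), G2/M and mitosis (-0.64), ATF4 targets (-0.25), oxidative phosphorylation (-0.1) and p53 targets (-0.13). Camera compares a list with the other genes, and the medians themselves were not tested. Of 19 fatty acid synthesis genes 6 were higher and 2 lower. Of 17 polyamine genes 5 were higher and 1 lower. No list call between 4 h and 16 h held with an estimated correlation. That of fatty acid synthesis was also lost under settings that included no filter, no mean-variance trend, the mean of probe sets and only the groups compared. Calls were also lost without single arrays, with a highest adjusted p of 0.124 for DNA replication (without 4 h replicate 1; 0.105 without 16 h replicate 3), 0.16 for cholesterol synthesis (without 16 h replicate 1; 0.106 without 4 h replicate 3) and 0.158 for fatty acid synthesis (without 16 h replicate 1; 0.0561 to 0.0899 without 0 h replicate 1, 4 h replicates 1 or 2 or 16 h replicate 2), 0.0725 for oxidative phosphorylation (without 4 h replicate 2) and 0.0921 for p53 targets (without 16 h replicate 1).

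Single genes that differed between 16 h and 4 h went up by log2 changes of 1.52 for KLK2, 0.55 for PMEPA1, 0.68 for KLK3 and 1.93 for TRPM8. Those that went down had changes of -1.95 for SGK1, -1.4 for SNAI2, -2.41 for MT1H, -2.11 for CKAP2L, -1.75 for DUS2, -1.41 for MAN1A1, -1.72 for TIPARP, -1.34 for PMAIP1, -0.86 for CDC42EP3 and -0.79 for IRS2. The calls of SGK1, SNAI2, MT1H, CKAP2L and IRS2 ended without several single arrays, as given above. Among probe sets with several gene symbols or none, which the gene tables leave out, 32 of 4588 were called at 4 h and 166 at 16 h against 0 h.

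Mitosis genes were lower at 16 h than at 0 h, with a list median of -0.551. Array scaling or a trend with signal was argued against, since 0% of 10000 random lists matched on mean signal had a median as low. A single array was also argued against, because the median was still -0.444 without 16 h replicate 3, the array whose removal weakened it most. Variation between cultures in the share of dividing cells stays open. An exact permutation test set the 16 h arrays apart from the other 6 (two-sided p = 0.0119, the smallest that 84 splits can give). The list p with an estimated correlation, however, was 0.334. The list was picked for its fall on these same arrays, so the permutation result in part restates that call. The centred mean level of the list was highest in replicate 1 at each time (0.354, 0.463 and -0.077 at 0 h, 4 h and 16 h). In replicate 2 it was 0.074, 0.089 and -0.466, and in replicate 3 it was 0.106, 0.083 and -0.626. The level was thus lowest at 16 h within each replicate number. DHT exposure and time in culture may each account for the fall, and the design holds no untreated cells at 16 h to separate them.

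Endoplasmic reticulum folding genes were higher and ATF4 targets lower at 16 h, with a difference of list medians of 0.636. Of 10000 random pairs of matched lists, 0% differed by as much, which argues against scaling or a signal trend. The difference was 0.581 without 16 h replicate 1, the array whose removal weakened it most, and the 16 h arrays stood apart from the other 6 (two-sided exact permutation p = 0.0119, the smallest possible). The 2 lists were picked for their opposite calls at 16 h, so the permutation result in part restates those calls. That result does not weigh against array-to-array spread. Scaling, a signal trend and a single array were argued against. A hypothesis is that the 2 branches of the stress response are set apart in treated cells. It was found and tested on the same data, neither list was called with an estimated correlation (adjusted p = 0.133 for each), and untreated cells at 16 h would be needed to test it against time in culture.

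Ribosome biogenesis genes were slightly lower at 4 h, with a list median of -0.102. A single array was argued against, since the median stayed at -0.081 without 4 h replicate 3, whose removal weakened it most. Array scaling or a trend with signal stays open: 0.06% of 10000 matched random lists had a median as low, but the upper 95% limit (exact binomial) of that share, 0.131%, lies above the 0.1% set for excluding it. Other lists leaned the same way at 4 h without being called, with 23 of 26 housekeeping genes (median -0.06, camera adjusted p = 0.111) and 36 of 38 cytosolic ribosomal proteins (median -0.05, adjusted p = 0.12) negative. The list p with an estimated correlation was 0.858, so the shift may be a fluctuation that these genes share, and no biological explanation was tested.

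Other splits of the same arrays bear on the counts of called genes. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most calls in each comparison (1 of 10 splits gave as many): 190 against a highest other of 1 for 4 h against 0 h, 987 against 0 for 16 h against 0 h, and 550 against 0 for 16 h against 4 h. Over the 3 times together, 1 of 100 groupings of the 9 arrays, the real one, gave 957 genes, and the highest of the others gave 418. That share, the smallest that 100 groupings can give, argues against chance for that count but does not exclude it.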

How the results depend on the processing

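No alternative in this part was chosen after its result was seen. Without a mean-variance trend, higher and lower genes numbered 92 and 18 at 4 h against 0 h, 289 were lower at 16 h against 0 h, 86 were higher and 93 lower at 16 h against 4 h, 493 differed over the 3 times and 80 calls were shared between 4 h and 16 h; the cause was not tested. With an adjusted p under 0.01, which can only remove calls, the counts were 87 and 16, 252 and 222, and 105 and 80, with 417 over the 3 times. With at least a 1.5-fold change, also a narrower criterion, 17 genes were lower at 4 h, 207 higher and 180 lower at 16 h, and 85 higher and 122 lower between 4 h and 16 h. With an estimated correlation 2 of the 28 list calls held, both of androgen-induced genes. With 1 array left out, and so fewer arrays, counts ran from 21 to 47 for genes lower at 4 h, 294 to 437 and 317 to 525 for genes higher and lower at 16 h, 123 to 274 and 120 to 256 between 4 h and 16 h, and 530 to 871 over the 3 times. ACACA changed sign between 4 h and 16 h with the mean of its probe sets (-0.075, against 0.55), because its probe sets disagree. Of 207 gene calls named by rule 147 were kept in all 9 single-array omissions, as were 21 of 28 list calls. No scaling moved the share of higher calls by over 10 percentage points. Whether replicate numbers pair the arrays stayed open. The 9 correlations of deviations between same-numbered arrays ran from -0.0539 to 0.0872, none over 0.1. The 18 between arrays with other numbers ran from -0.119 to 0.0538. In both other groups, 6 of 9 arrays correlated best with their own number. The replicate block gave 143 and 53, 490 and 629, and 293 and 308 genes, 1021 over the 3 times, all within 1.5 times the counts without it; IGKC and LRIG3 at 4 h (adjusted p = 0.0719 and 0.0604), IL15RA (0.0561) and the fatty acid list between 4 h and 16 h were not called with it. Signal over background limits the dimmest genes, whose folds are bounds.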

Other observations

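The families of metallothioneins, zinc transporters and glycosylation genes below, and all of their tests, were chosen after the gene results had been seen.

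Of 7 measured metallothionein genes, which bind zinc and copper, 2 fell at 16 h against 0 h, 5 did not pass the test and none rose (median log2 change -0.73, negative under each scaling tried). The family was picked because MT1H had the largest fall among called genes whose arrays did not overlap, and its list test includes MT1H, so that test (camera adjusted p = 0.02 over 3 families, p = 0.175 with an estimated correlation) in part restates the fall and is not evidence for the family. Between 4 h and 16 h the list was also called downward (camera adjusted p = 0.00121, p = 0.0915 with an estimated correlation), with the same limit. At 16 h against 0 h MT1X changed by -1.10 ± 0.26 and MT1H by -2.62 ± 0.51 (not called without a mean-variance trend, adjusted p = 0.0504), while MT3 changed by 0.17 ± 0.22. Probes of such near-identical genes may cross-hybridise. The number of family probe sets that rose by over 2 SE at 16 h was 0, which leaves that explanation open, although the 2 probe sets for MT1E changed by only -0.34 ± 0.20 and 0.01 ± 0.33.

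A hypothesis that the falls of MT1H and MT1X went with altered zinc transport was not settled. Of 20 zinc transporter genes 2 rose and none fell at 16 h, namely SLC39A10 (1.18 ± 0.07) and SLC39A6 (0.56 ± 0.07), both importers. The family had an unadjusted list p of 0.0452, an adjusted p of 0.0678 over 3 families and a p of 0.165 with an estimated correlation, with a median of 0.00. The criterion for this family was changed from the unadjusted to the adjusted p after its value had been seen. The exporter SLC30A1, a metal-responsive gene, changed by -0.54 ± 0.31 and did not pass the test. Between 4 h and 16 h, which the criterion did not cover, 3 zinc transporter genes were higher and none lower. The family list was called upward there (camera adjusted p = 0.0055 over 3 families, but p = 0.0616 with an estimated correlation).

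Genes that build glycans or supply nucleotide sugars changed in both directions at 16 h. Of 89 measured, 9 were higher, 4 were lower and 76 did not pass the test. CSGALNACT1, which starts chondroitin chains, rose by 2.50 ± 0.34 on the log2 scale, and the branching enzyme GCNT1 rose by 0.92 ± 0.08. HS6ST2, a heparan sulfotransferase, fell by 1.05 ± 0.17, and the sialyltransferase ST3GAL1 fell by 0.66 ± 0.06. The idea of a coordinated rise was not borne out, with an unadjusted list p of 0.191 and a median of 0.01.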
